A study of Danio rerio with 4 samples.

How the data were processed

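Whole zebrafish embryos injected with Salmonella typhimurium or with PBS were profiled by digital gene expression with NlaIII tags. Per the labels' protocols, equal amounts of RNA from 3 biological samples were pooled per condition, and mRNA was captured on oligo(dT) beads. The cDNA was cut with NlaIII, the bead-bound 3′ fragments were kept, and MmeI released a short tag downstream of each CATG. Tags were amplified by PCR without molecular identifiers. Per the series' design text, the libraries were run on an Illumina Genome Analyzer II, and the Illumina pipeline called the bases, extracted tags of 17 bases and counted them. Each deposited file holds, for 1 lane, a tag sequence and its raw tag count, with no normalization and no gene name, as read from the files. The version of that pipeline is not given in the sources used here. No alignment was needed to make such files, and none was made here.

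The samples fell into 2 groups by their source label, Salmonella and PBS, with 2 lanes each. Replicate 1 is the lane loaded with 2 pmol of cDNA and replicate 2 the lane loaded with 3 pmol. Both lanes of a group come from the same library, so their counts were summed, and each condition had 1 biological sample. The test was designed for genes, with a fallback to tags if no transcript sequences were at hand. Only tables of gene names came with the data, so tags were the tested feature throughout. The tests of predefined gene lists, the panel of named immune genes, and the choices of how tags are assigned to genes were not run.

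The tag of 17 A, which names no transcript, was left out of library totals and tests. It held 1.78% (95% Wilson interval 1.77 to 1.79) and 0.777% (0.769 to 0.785) of the counts in the 2 pmol and 3 pmol lanes of the infected library. In the PBS library it held 0.743% (0.735 to 0.750) and 0.130% (0.127 to 0.134). The remaining totals were 9889899 counts for the infected and 9541033 for the PBS library. Tags seen once in a lane held 6.78% and 8.51% of the counts in the infected lanes and 7.07% and 8.00% in the PBS lanes.

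Each tag with 10 or more counts over both libraries was tested with a two-sided Fisher's exact test of its count against the rest of its library. P-values were adjusted by Benjamini-Hochberg over the 112886 tags tested, and the other 1334828 tags were not tested. A tag was called when the adjusted p was under 0.05, the fold of CPM (counts per 1000000 counts) was 2 or more after adding 0.5 tags to each count, and the 2 pmol pair and the 3 pmol pair of lanes had the same direction. The adjusted p alone was met by 16109 tags, 10831 of them higher and 5278 lower in the infected library. The rule on lane pairs removed 24 tags that met the other criteria. Intervals of a tag's ratio between the libraries are 95% exact (Clopper-Pearson) intervals of the share of a tag's counts that lie in the infected library, given both totals. Intervals of shares of counts are 95% Wilson intervals. A count of 0 was bounded by 3 counts, or 0.303 CPM in the infected and 0.314 CPM in the PBS library. These intervals and floors cover counting error only. In the closing section, intervals of the ratio of higher to lower tags are 95% normal intervals on the log scale from the 2 numbers of calls, and bootstrap intervals resample tags or pairs of tags. Both treat tags as independent, which they are not, and describe the spread between tags.

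The named tags were chosen by a fixed rule, which takes the 10 called tags with the largest fold in each direction among those with at least 20 CPM in the library where they are more abundant and 100 counts over both libraries. Other tags named in the text were chosen after their values were seen. The values of 1 further abundant tag are not reported here. Tags of neighbouring sites were paired when one tag held an inner CATG and the sequence after it matched the start of another tag over 10 or more bases.

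The test was checked on simulated data with the libraries' own totals and abundances. Counts were drawn with counting error only (Poisson), around the same abundances in all lanes apart from the changed tags. Over 116070 simulated tags the test called 4 unchanged tags. It recovered 38% of tags changed 2-fold, 94% of those changed 3-fold, 98% of those changed 4-fold and 100% of those changed 8-fold, with 50 tags per fold and 100 or more counts each. A 2-fold change lies at the fold threshold itself. Repeat lanes of the real libraries differed by more than counting error, so the 4 calls are not an error rate for these data.

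The design, the rule for named tags and the following alternatives were set before the data were examined: TMM and median-of-ratios scaling, no minimum count and a minimum of 50, fold thresholds of 1.5 and 4, tags seen once left out, each lane and each pair of lanes left out, edgeR's quasi-likelihood test over the 4 lanes with and without the lane number as a block, DESeq2 over the 4 lanes, and edgeR's likelihood ratio test with an assumed biological coefficient of variation of 0.2 or 0.4. A model over lanes measures only the spread between sequencing runs, which is why it was not the main test. Alternatives added after the data were seen are named in the closing section. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.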

Results

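The series addressed how the transcriptome of the whole zebrafish embryo differs after infection with Salmonella typhimurium, a Gram-negative bacterium that multiplies inside phagocytes. Embryos received DsRED-labelled bacteria, or an equal volume of phosphate-buffered saline (PBS), into the caudal vein at 27 hours post fertilization. They were collected 8 hours later, at an age of 35 hours post fertilization. RNA from 3 infection experiments was pooled for each condition, and 1 library was made from each pool. The assay was digital gene expression (DGE), which counts a short sequence next to an NlaIII restriction site (CATG) near the 3′ end of each polyadenylated transcript. Each measured item was thus a tag of 17 bases. Tags are named by sequence because no transcript sequences were used here, so neither their genes nor their positions in the genome are given.

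Each library was sequenced in 2 lanes, loaded with 2 pmol and with 3 pmol of cDNA. The infected library gave 5421004 tags in the 2 pmol lane and 4601216 in the 3 pmol lane. The PBS library gave 5024447 and 4559832. Together the 4 lanes held 1447715 distinct tags, of which 112886 had 10 or more counts and were tested. These tested tags held 88.8% of all counts. The lanes of a library are repeat runs of the same cDNA, so the design has 1 biological sample per condition and no replicate check. Tests and intervals in the comparisons that follow compare these 2 libraries, not the conditions, and cover counting error only, because the tags carry no molecular identifiers.

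With scaling by total count and a fold of 2, more tags were called higher than lower in the infected library. By a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, a fold of at least 2 and the same direction in both pairs of lanes, 8186 tags (7.25% of those tested) were higher and 2197 (1.95%) were lower in the infected library. The higher tags made up 5.70% of the infected library's counts (95% Wilson interval 5.68 to 5.71) and 1.92% of the PBS library's (1.91 to 1.93). The lower tags made up 0.439% (0.435 to 0.443) and 1.17% (1.16 to 1.18). Among the 6821 tags with at least 20 CPM (counts per 1000000 counts) in the library where they were more abundant and at least 100 counts in all, 404 were higher and 67 were lower. Of these 404, 345 differed by 1 to 2 on the log2 scale, 47 by 2 to 3 and 12 by 3 or more. Of the 67 lower tags, 62 lay between 1 and 2, and the remaining 5 between 2 and 3.

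The direction of the imbalance held under other scalings, but its size did not. Higher tags were 78.8% of all calls with scaling by total count, 67.3% with TMM scaling and 66.2% with median-of-ratios scaling. In the set with at least 20 CPM the values were 85.8%, 70.4% and 67.6%. TMM moved every log2 difference by -0.13 and median-of-ratios scaling by -0.14, and the values given here are to be read against those shifts. These pools cannot measure the spread between biological samples. With an assumed biological coefficient of variation of 0.2, edgeR's likelihood ratio test, which also uses TMM scaling, called 1968 tags higher and 387 lower. With 0.4 it called 2 higher, CTAAAATAAATTCATTT and TTATGAAATTTTTTATG, and 0 lower. With that value, 4570 higher and 1288 lower tags had an unadjusted p under 0.05. Together these are close to a share of 0.05 of the tags tested, but with no difference the 2 directions would be about even. Since 0.4 is an assumed value, that share cannot tell whether the calls match those of no difference. Leaving out single lanes, which lowers the depth, gave 4380 to 6845 higher and 807 to 1941 lower tags, the fewest higher ones without the PBS 3 pmol lane and the fewest lower ones without the infected 2 pmol lane.

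**Figure D1:**
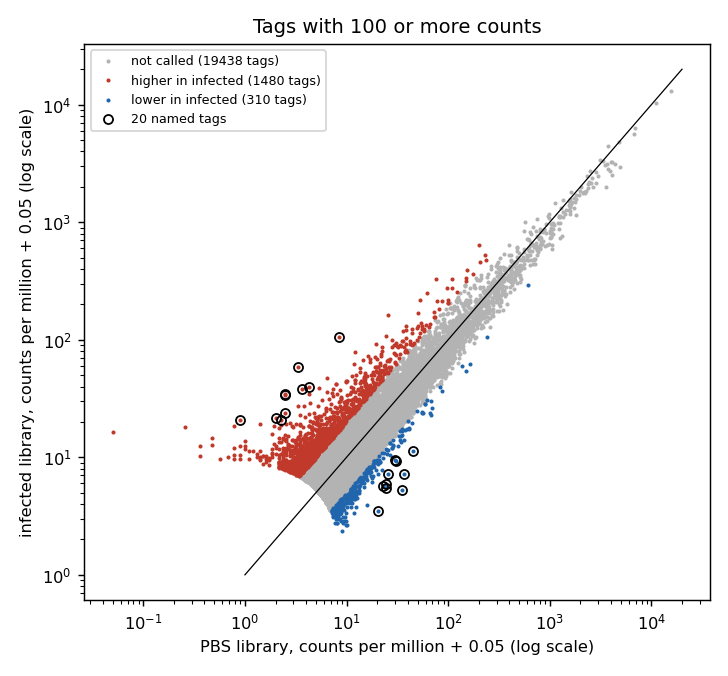
Abundance of each tag with 100 or more counts in the PBS library (x axis) and in the infected library (y axis), both in CPM plus 0.05 on a log scale. Red points are the 1480 tags higher in the infected library, blue points the 310 lower ones, grey points the 19438 tags not called, circles the 20 named tags, and the line marks equal abundance.

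The largest difference among tags with at least 20 CPM was that of TTAAAATCATTTTTGGC, with 205 counts in the infected library and 8 in the PBS library, a fold of 23.3 (95% interval of the ratio 12.3 to 58.0; adjusted p = 1.7e-46, Fisher's exact test). GGGCAAAGTAGCTACAT followed with 576 counts against 31, a fold of 17.7 (12.5 to 26.6). The most abundant of the 10 named higher tags was ATGGGTTTCCTAATGGC, at 105.0 CPM in the infected library and 8.38 CPM in the PBS library, a fold of 12.4 (9.96 to 15.9). TCAATGCTGTTGATGTC, with 341 counts against 23, was higher by 3.81 on the log2 scale (ratio interval 9.37 to 22.9). GTATTTTTAGCCTGTCA, with 333 counts against 23, was higher by 3.78 (9.15 to 22.3). GTACATAGTGACCCCTT was higher by 3.41 on the log2 scale, TACACAATAAAATAAGC by 3.39, ATTGAGAAGATGATAGC by 3.27, CACAGGGAGATGAAGGA by 3.22 and TTATGAAATTTTTTATA by 3.21. The last of these held 3.98 in the 2 pmol pair of lanes and 2.65 in the 3 pmol pair.

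The lower tags differed by smaller factors. GATTAAAAGCACTGTTA had 52 counts in the infected library and 332 in the PBS library, a fold of 6.56 lower (95% interval 4.93 to 9.05; adjusted p = 1.1e-50, Fisher's exact test). GGTGCATAAATAAAACT was 5.78-fold lower (4.05 to 8.70) and TGTTCTGTATGTTGCTT 5.11-fold lower (3.97 to 6.73). TCAGGCCTGTGCTTTGT, at 54 counts against 231, was 4.40-fold lower (3.28 to 6.08), and TTTTTACCAAAAAATTG was 4.17-fold lower (3.14 to 5.70). TAAAACATTTTAAACAG and GGAAACCTGGGATTCTT were each 3.99-fold lower. The log2 difference was -1.81 for AAAATTAAATGTACTTT, -1.73 for CTGTGACAGTTATTTTT and -1.65 for AAAACCTTTTCAGCAGC. None of the 20 passed the threshold with an assumed biological coefficient of variation of 0.4.

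**Figure D2:**
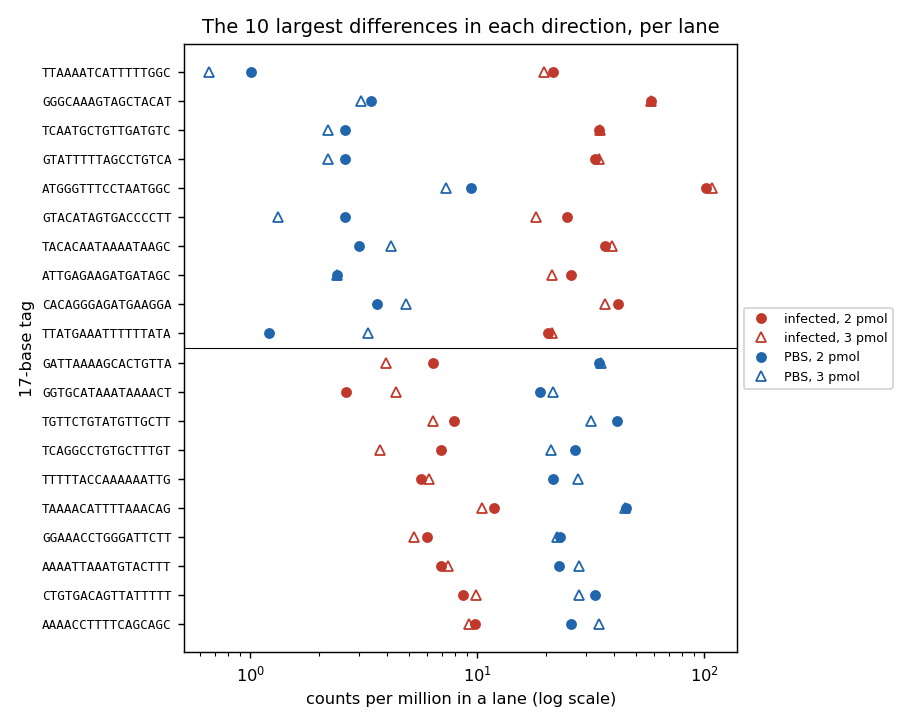
CPM (log scale) of the 10 tags with the largest fold in each direction, in the 2 lanes of the infected library (red) and the 2 lanes of the PBS library (blue), with filled circles for 2 pmol and open triangles for 3 pmol lanes. For each tag both infected lanes lie on the same side of both PBS lanes. ATGGGTTTCCTAATGGC is the most abundant, at 105.0 CPM in the infected library.

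Tags with high counts in both libraries were chosen after their values were seen. TTCAATGTCTTGAAAAG stood at 645 CPM in the infected library and 201 CPM in the PBS library, a log2 difference of 1.68 (95% interval of the ratio 3.04 to 3.37). TGAATTATTCAATTAAA stood at 330.4 CPM against 75.7 CPM, a fold of 4.36 (4.03 to 4.74). The most abundant lower tag, GTTTCAGAGACACAGTT, stood at 292 CPM against 612 CPM, a log2 difference of -1.07. None of the 163 tested tags with 10000 or more counts passed the fold of 2. Their median log2 difference was -0.20, and they held 22.7% of the infected library's counts and 26.0% of the PBS library's. The most abundant tag of both libraries, CATCTCCTGTCTGGTGG, had 13154 CPM in the infected library and 15723 CPM in the PBS library, a log2 difference of -0.26. ATTTTTTGAAACATTCA, at 2963 CPM against 4875 CPM, had a log2 difference of -0.72, and TCTCTGCACTTCATGAT, at 4459 CPM against 3749 CPM, had 0.25. The latter holds an inner CATG and is thus among the tags with an uncut site described below. It gave 44095 of their 321157 counts in the infected library and 35774 of 255747 in the PBS library.

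Some tags were counted in the infected library and had 0 counts in the PBS library, where 3 counts correspond to 0.314 CPM. With a minimum of 20 counts there were 49 such tags, each seen in both infected lanes, and 3 tags with the opposite pattern. With a minimum of 10 counts there were 674 and 103. The most abundant, CTAAAATAAATTCATTT, had 79 and 83 counts in the infected lanes and was at least 52.1-fold higher than the floor of 3 counts over the PBS library. The exact 95% interval of its ratio, which also takes in the error of its own count, starts at 41.9. TGTTGATGCTCAAGTGA had 27 and 23 counts and was at least 16.1-fold higher against that floor (exact lower limit 12.6). The 3 tags with 0 counts in the infected library were AAGTCACCGTAAAAGAA with 25 counts in the PBS library, TTAATTGAAACAAATCA with 23 and GTGTTACTGGTCATATC with 22. The first of these was at least 8.64-fold lower in the infected library against a floor of 3 counts there (exact lower limit 6.52). These tags were also chosen after their values were seen.

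The difference between the libraries varied with the abundance and base composition of the tags. The median log2 difference was 0.19 for tags with 10 to 19 counts, 0.07 for those with 100 to 199, -0.05 for those with 500 to 999 and -0.20 for those with 10000 or more. Higher tags held on average 6.90 G or C bases of 17 and lower tags 5.66, against 6.35 for all tested tags. Tags that still contained the CATG site inside their sequence, which complete digestion would have removed, made up 3.25% of the infected library's counts (95% Wilson interval 3.24 to 3.26) and 2.68% of the PBS library's (2.67 to 2.69). By lane the shares were 3.26% and 3.23% in the infected library and 2.72% and 2.64% in the PBS library.

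**Figure D3:**
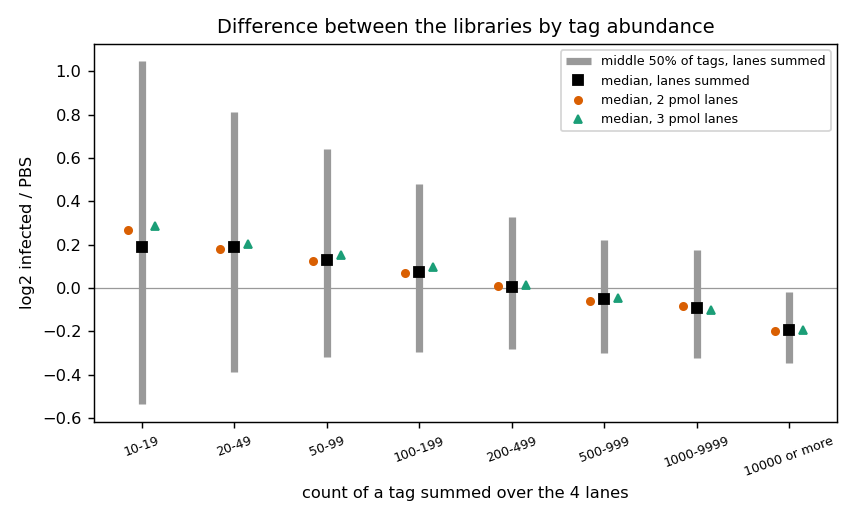
Log2 ratio of the infected over the PBS library by the count of a tag summed over the 4 lanes, with the median (black squares) and the middle 50% of tags (grey bars) from the summed lanes, and the medians of the 2 pmol (orange) and 3 pmol (green) lane pairs. The median of the summed lanes falls from 0.19 in the class of 10 to 19 counts to -0.20 in the class of 10000 or more. That of the 2 pmol pair falls from 0.27 to -0.20 and that of the 3 pmol pair from 0.29 to -0.20.

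The repeat lanes gave the size of differences between sequencing runs, and not of those between library preparations. Between the lanes of the infected library, the same adjusted p and fold thresholds, without the condition on lane pairs, called 77 of 76195 tags (0.101%), and the chi-square statistic per degree of freedom was 1.37. Between the lanes of the PBS library they called 184 of 66264 tags (0.278%), with a statistic of 1.64. Repeat lanes thus differed by more than counting error alone. Any infected lane against any PBS lane gave between 3690 and 6921 calls, or 5.26% to 9.58% of tags tested, with statistics of 3.88 to 5.15. Across the 11674 tags with 200 or more counts, the log2 differences of the 2 pmol and the 3 pmol lane pairs correlated with Pearson's r = 0.824 and Spearman's rho = 0.763. This correlation is across tags, which are not independent replicates, and both pairs of lanes come from the same 2 libraries.

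**Figure D4:**
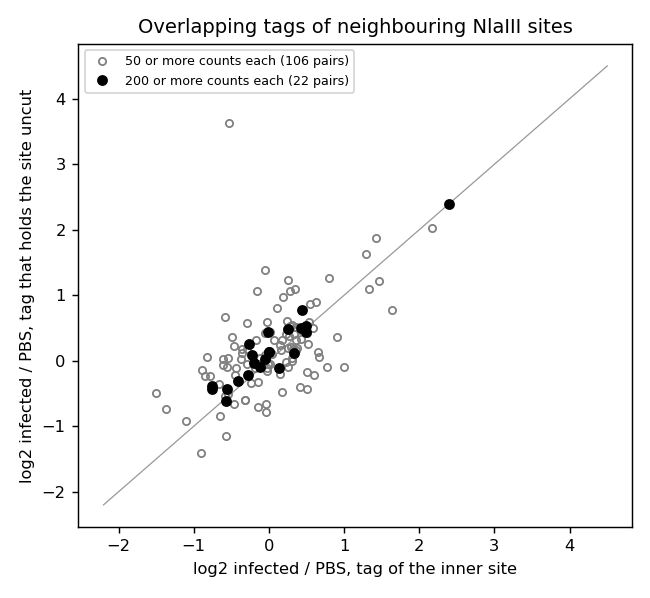
Log2 ratio of infected over PBS for pairs of overlapping tags from neighbouring NlaIII sites, with the inner site's own tag on the x axis and the tag that holds that site uncut on the y axis. Open circles are pairs with 50 or more counts per tag, filled circles the 22 pairs with 200 or more, and the line marks equality. Among the 22 pairs the values correlated with r = 0.954.

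Pairs of tags from neighbouring NlaIII sites gave a check inside each library. A tag that holds an uncut site overlaps the tag of that site by 10 or more bases, so both can be joined without a reference. Across 22 such pairs with 200 or more counts per tag, the log2 differences of both tags correlated with Pearson's r = 0.954 and Spearman's rho = 0.880. Across 128 pairs with 50 or more counts per tag, r was 0.588 and rho also 0.588. These correlations are across pairs within the same libraries, and pairs are not independent replicates. CCATGTACAAAGAAAAT and TACAAAGAAAATGACCT, the pair with the largest difference among the 22, were 5.27-fold and 5.28-fold higher in the infected library.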

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

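The tag of 17 A, which was outside the main measurement, was more frequent in the infected library than in the PBS library at each amount of cDNA loaded. It made up 1.78% of the counts in the infected 2 pmol lane against 0.743% in the PBS 2 pmol lane, and 0.777% in the infected 3 pmol lane against 0.130% in the PBS 3 pmol lane. The share also differed between the repeat lanes of each library. Between the PBS lanes it differed by a larger factor than between the infected and PBS 2 pmol lanes, and by a smaller one than between the 3 pmol lanes. No biological explanation was tested for it.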

How the results depend on the processing

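Alternatives that keep the 17-A tag, leave out low-complexity and adapter tags or tags near a far more abundant one, centre by GC or by GC and abundance, or take totals without tags of 10000 or more counts were added after the data were seen, as were the separate counts for tags of 20 CPM or more. Every alternative that called tags in both directions gave more higher than lower ones, and none reversed a named tag. Of 480 values of named tags over 24 alternatives, 455 stayed past the threshold and 25 did not, 20 of these with an assumed coefficient of variation of 0.4 and 5 with a fold threshold of 4. In what follows, counts are higher then lower, and the cause of a change was not tested unless the setting itself sets it. Without a minimum count, 3917 and 662 tags were called, over more tests. With a minimum of 50 counts there were 3571 and 898, over fewer. A fold threshold of 1.5 gave 9939 and 3650 tags (881 and 568 at 20 CPM or more), and a threshold of 4 gave 3766 and 886 (59 and 5, the 5 being the first 5 named lower tags). TMM scaling gave 6453 and 3141 (311 and 131), and median-of-ratios scaling 6383 and 3255 (300 and 144). Leaving out lanes, which lowers the depth, gave 3124 to 6845 higher and 807 to 1941 lower tags, and 380 to 483 and 59 to 115 at 20 CPM or more. By lane, the counts were 4812 and 807 without the infected 2 pmol lane, 6845 and 1672 without the infected 3 pmol lane (114 lower at 20 CPM or more), 4873 and 1941 without the PBS 2 pmol lane (115 lower at 20 CPM or more), 4380 and 1061 without the PBS 3 pmol lane, 3124 and 1001 with the 3 pmol lanes alone and 4100 and 928 with the 2 pmol lanes alone. edgeR's quasi-likelihood test over the 4 lanes called 4472 and 1713 tags (312 and 128). With the lane number as a replicate block it called 1156 and 366 tags (309 and 127), with few residual degrees of freedom. Lanes of the same number share only the amount of cDNA loaded, and the log2 ratio of lane 2 over lane 1 correlated between the libraries with r = 0.322 across tags, which are not independent replicates. DESeq2 over the 4 lanes called 772 and 227 tags (299 and 121) and gave no adjusted p for 78790 tags. With an assumed coefficient of variation of 0.2, edgeR called 1968 and 387 tags (124 and 22). With 0.4 it called 2 and 0 (0 and 0 at 20 CPM or more), CTAAAATAAATTCATTT and TTATGAAATTTTTTATG being the 2. At an unadjusted p under 0.05 there were 4570 and 1288. Together these are close to a share of 0.05, but the directions are uneven and 0.4 is an assumed value. That share thus cannot tell whether the calls match those of no difference. Centring by GC and abundance gave 6058 and 3111 tags (411 and 61), so that higher tags fell to 66.1% of all calls but were 87.1% of those at 20 CPM or more. The alternatives planned for genes were not run: tags at the 3′-most site, the most abundant tag per gene, shared tags split between genes, genes against tags, and medians of gene lists. Depth limits what can be said of the 1334828 tags under 10 counts, which were not tested.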

Other observations

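The tests on near-identical partner tags, on tags without the AATAAA motif, on inner NlaIII sites and on pairs of neighbouring sites were chosen after the main result was seen.

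Many called tags had an abundant partner that differed from them by 1 base, as tags of recently duplicated genes or of alleles would. Among tags with 100 or more counts, 107 of the 1480 higher tags and 37 of the 310 lower tags had a partner with 0.1 to 10 times their count. Partners of higher tags mostly moved the same way, with a median log2 difference of 1.06, and 55 of the 107 were themselves called higher. AGTACTGTCAGTTATCA was higher by 2.67 and its partner AGTACTGTCAGTTATCC by 2.86. They differ by C17A, the partner's base first and the position counted from the base after CATG. CCAAATTCGAGGAGATC was higher by 2.01 and its partner CCAAATTTGAGGAGATC by 1.87, with T8C between them. Partners of lower tags had a median log2 difference of -0.29, and 23 of the 37 lay within 0.5 of 0, against 21 of the 107 partners of higher tags (p = 5.9e-06, Fisher's exact test, two-sided, over tags, which are not independent replicates). TAAGCAAATGTTCAATG, for example, stood at -1.27 and its partner TAAGTAAATGTTCAATG, with T5C between them, at 0.14. TATTCTGACGGTTTCCA stood at -1.43 and its partner TATTCTGACGGTGTCCA, with G13T between them, at -0.11. Where both tags of a pair were called, both could enter these counts. Partners called the same way numbered 55 for higher and 2 for lower tags, so the p-value is not a test over pairs. Higher tags also lay further from 0, at a median of 1.42 against -1.16. Across all 1074 pairs of such tags, called or not, the log2 differences of both tags correlated with Pearson's r = 0.610.

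An explanation by alleles of a transcript in other proportions in the 2 pools of embryos would move partners in opposite directions. The signed median, taken as positive where the partner moves with the called tag, was 1.06 (95% bootstrap interval 0.863 to 1.39) for higher tags and 0.292 (0.177 to 0.506) for lower tags. The median of higher tags argues against alleles as the account of that whole set. For lower tags the median was also above 0, but the test cannot decide. A partner more abundant than the called tag would move little, and 23 of the 37 partners lay within 0.5 of 0. Single pairs of lower tags, such as TAAGCAAATGTTCAATG and its partner, may still be alleles or copies of a gene, and this cannot be decided without the transcript sequences.

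Higher tags outnumbered lower tags by 3.73 to 1, and 3 technical explanations were weighed against a response to infection. GC content as the whole cause was argued against for tags of 20 CPM or more only. Each GC class was centred on the median of its tags with 200 or more counts. The ratio of all calls then stood at 4.48 (95% interval 4.26 to 4.71), above the bound of 2. Tags with fewer counts were thus not centred on their own medians, and centring the abundance classes as well lowered the ratio to 1.95. Among tags of 20 CPM or more, 415 were higher and 62 lower after GC centring, and 411 and 61 after both. Scaling stayed open, because median-of-ratios scaling lowered the ratio to 1.96 (1.88 to 2.05), between the bounds of 1.5 and 2 set for it. Less complete NlaIII digestion of the infected library could raise tags upstream of the last site. Tags with the polyadenylation motif AATAAA were taken to lie beside the tail, though no positions are known here. Such tags would then be spared. Their ratio after GC centring was 1.17 (0.910 to 1.52), with 128 higher and 109 lower of 3450. It was 1.12 (100 higher and 89 lower) at 10 to 99 counts and 1.40 (0.789 to 2.49) at 100 or more, against 4.51 (4.27 to 4.77) and 5.71 (5.00 to 6.52) for tags without the motif. The upper bound of 1.52 passes the limit of 1.5 set for it, so digestion also stays open, as does a response to infection, which has no replicate pool here.

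Other values bear on digestion. Tags with an uncut inner site had a 1.21 times larger share in the infected library (1.22 in the 3 pmol pair of lanes). In pairs of neighbouring sites with 50 or more counts per tag, the tag with the uncut site lay above the inner site's own tag by a median of 0.08 on the log2 scale (95% bootstrap interval 0.04 to 0.17), in 77 of 128 pairs. With 200 or more counts per tag the median was 0.11 (0.04 to 0.22), in 17 of 22 pairs. Median shifts of 0.08 and 0.11 lie well below the fold of 2 needed for a call. These shifts span 1 uncut site, in pairs with both tags counted, so they do not bound the effect on tags with more sites downstream. The share of tags with an uncut inner site differed by more, 0.28 on the log2 scale. Whether digestion moved tags past the threshold was not tested. Scaling moves all tags alike, so it cannot produce a gap between tags with and without AATAAA. At 100 or more counts the GC-centred median was -0.086 (-0.122 to -0.064) with the motif and 0.043 (0.036 to 0.051) without it. This gap goes the way less complete digestion predicts, but the limit set for that test was passed. The medians were centred by GC only. Since the median also fell with abundance, a difference in abundance between the 2 sets was not separated from the gap.

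Many cytokine and early-response transcripts carry AU-rich elements, so a hypothesis was that tags with the core ATTTA are more frequent among higher tags. The motif was in 42 of the 1480 higher tags with 100 or more counts (2.84%) and in 774 of the 19438 tags not called (3.98%). Within GC classes the odds ratio was 0.955 (95% bootstrap interval 0.682 to 1.26). The longer cores had odds ratios of 1.16 (0.696 to 1.82) for TATTTA, in 17 higher tags, and 1.74 (0.743 to 3.09) for TATTTAT, in 9 higher tags. All 3 intervals include 1, so no enrichment was detected at these numbers, and the interval of ATTTA passes the bound of 1.2 below which one was to be excluded. A tag covers only 17 bases of a transcript, which limits this test.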
